A study of Bos taurus with 6 samples.

How the data were processed

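The data comprised 6 arrays of primary bovine aortic endothelial cells, 3 from basal cultures and 3 from cultures treated with 5 ng/ml TGF-beta 1 for 24 hours. Biotin-labelled RNA was made from 4 µg of total RNA extracted on columns and hybridised to an Affymetrix bovine array, per the labels. The deposited values are log2 expression, made with RMA and the affy package per the submitters' processing notes, which give no versions. RMA corrects background, normalizes arrays to a common distribution by quantiles and summarises the probes of a probe set, so it compresses changes near background and near saturation and gives no detection call. Each array column was assigned to its sample by the label, and 0 columns were left unused.

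The table held 24128 probe sets. The 112 AFFX control probe sets were kept out, which left 24016. Of these the array annotation gave 1 gene symbol for 13292, several for 86 and none for 10638. Of the probe sets with 1 symbol, 13263 were matched by gene identifier to the RefSeq gene table of assembly ARS-UCD2.0, and 0 symbols changed. That table served for names only and no coordinates are given, since the array annotation names no build. Probe sets with several symbols were tested and not named. A gene was represented by its probe set with the highest mean over all 6 arrays, which gave 9162 genes.

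Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, group as the only term, 4 residual degrees of freedom). The estimated prior had 2.14 degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg over all probe sets or over all genes, with a threshold of 0.05. No filter on dim probe sets was applied. Standard errors and 95% intervals are those of the moderated fit. Of 32 gene lists, all with at least 5 measured members, the shift was tested with camera at a preset correlation of 0.01 between genes and adjusted over the lists. Members were also adjusted over the list alone, with the p-values of the same fit. The lists covered SMAD2/3 targets, BMP and ALK1 targets, TGF-beta ligands and receptors, collagens, other extracellular matrix, the mesenchymal and contractile genes, endothelial identity, vasoactive mediators, reactive oxygen, the respiratory chain, cell cycle, inflammation, interferon response, proteases, growth factors, Notch, integrins and junctions, glycolysis and hypoxia, cholesterol and fatty acid synthesis, endoplasmic reticulum stress, YAP/TAZ and SRF targets, immediate early genes and apoptosis. Ribosomal and housekeeping genes served as technical comparison, and markers of smooth muscle, fibroblast, pericyte, leukocyte, erythroid, epithelial or mesothelial and adipocyte cells covered other cell types.

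The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with the groups apart, then from each list the 4 members with the smallest unadjusted p, and always a set of 24 genes of TGF-beta signalling and endothelial function. It gave 155 genes. Identifiers without a gene name were passed over. SMAD6 and SMAD7 of that set were not analysed here, and 1 further item is not reported here. Genes named outside the rule were chosen after their values were seen, which holds for EED, HHEX and RAMP2 in the report.

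The fits were tested on simulated data with the real genes' spread, 3 arrays against 3 and 9162 genes. Over 10 simulations 5.7% of genes changed by 0.5 log2 were recovered, 50.3% at 1 and 77% at 2, with the right sign in 100% of them, and 54 of 937 calls were false. A list shifted by -0.5 was found in 20 of 20 simulations and 0 of 620 unshifted lists were called. The simulated genes varied independently and held no structure between arrays, so these counts do not show how often lists or genes are falsely called in the real arrays.

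Alternatives were a further quantile normalization, centring on array medians, limma-trend, robust eBayes, array weights, the replicate number as a block, filters at the 25th percentile and the median of mean expression, leaving out each array, a minimum of 1.5-fold, treat against 1.2-fold, thresholds of 0.1 and 0.01, other ways to represent a gene, camera with an estimated correlation or on ranks, and fry. The fit with a 2-level block that sets basal 1, basal 2 and TGFB1 1 against the others was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.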

Results

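Primary bovine aortic endothelial cells were freed from the vessel wall with collagenase and cultured, and plates of them received 5 ng/ml TGF-beta 1 for 24 hours or no treatment. TGF-beta 1 is a cytokine that endothelial cells sense through the type II receptor TGFBR2 and the type I receptors TGFBR1 and ACVRL1 (ALK1). Gene expression was measured on an Affymetrix bovine array, with 3 arrays of untreated (basal) and 3 of treated cultures. The labels describe triplicates from 3 cultures. They do not say whether these came from separate animals or whether a basal and a treated array shared a culture. The p-values therefore rest on the spread between the arrays of a group, whatever its source. Each array gave log2 expression for 24016 probe sets, which represented 9162 named genes. Array medians lay between 5.88 and 5.92, and array maxima between 13.93 and 14.03. The number of arrays limits the precision of every value.

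The arrays did not part by treatment alone. The first principal component held 63.4% of the variance and the second 24.7%. On the first component basal 1 lay at -67.8, basal 2 at -38.8 and TGFB1 1 at -10.3, against 36.0 for basal 3, 39.5 for TGFB1 2 and 41.4 for TGFB1 3. The second component set the groups apart, with basal arrays from -38.2 to -10.9 and treated arrays from 5.74 to 48.0. Basal 3 correlated at 0.987 with TGFB1 3 across probe sets and at 0.942 with basal 1. The highest correlation was 0.996, between TGFB1 2 and TGFB1 3, and the lowest 0.940, between basal 1 and TGFB1 3. Correlations across probe sets describe pairs of arrays, since probe sets are not independent replicates.

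**Figure D1:**
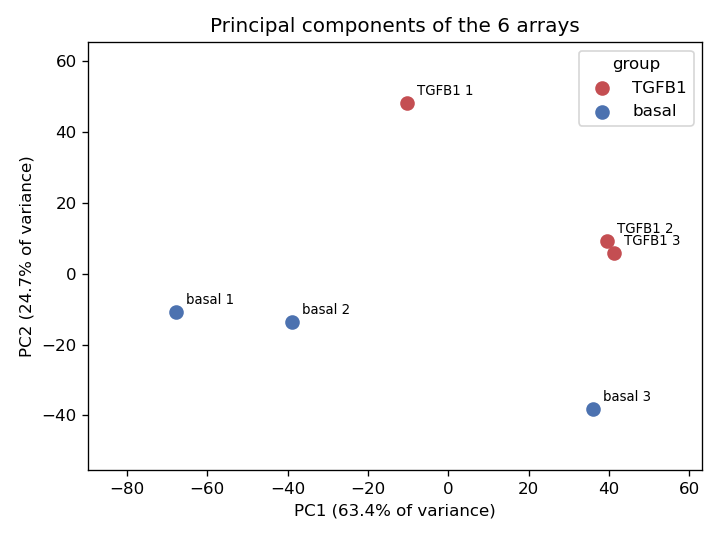
Position of the 6 arrays on the first principal component (horizontal axis, 63.4% of the variance) and the second (vertical axis, 24.7%), from log2 expression of all probe sets, with basal and TGFB1 arrays in separate colours. Basal arrays lie at or below -10.9 on the second component and treated arrays at or above 5.74, while basal 3 lies at 36.0 on the first component beside TGFB1 2 and TGFB1 3.

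The comparison of treated with basal cultures addressed what TGF-beta 1 changes in the transcriptome of these cells. Among genes with a single name, the largest rise was that of LOXL4 (Entrez gene 281904), a lysyl oxidase that cross-links collagen and elastin. It went from 5.45 ± 0.72 to 10.96 ± 0.15 log2 (mean ± SD, n = 3 each), a 45.3-fold rise with a 95% interval of 25 to 82.1 and a limma adjusted p = 0.0155. SELE, the E-selectin that captures leukocytes, rose 9.40-fold (6.49 to 13.6) and CXCL12, a leukocyte chemokine, rose 8.66-fold (5.43 to 13.8). The largest fall among them was that of CLDN5 (Entrez gene 617453), the claudin of endothelial tight junctions, from 9.36 ± 0.82 to 6.19 ± 0.28 log2, an 8.98-fold fall (4.46 to 18.1, limma adjusted p = 0.0371). EPAS1, a hypoxia-inducible transcription factor abundant in endothelium, fell 8.86-fold (5.73 to 13.7, limma adjusted p = 0.0188). A probe set annotated to several genes, and so not named, fell by 3.52 log2 (limma adjusted p = 0.000985).

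Of the 9162 genes, 158 passed the limma threshold, 51 higher and 107 lower after TGF-beta 1, and 1598 genes had an unadjusted p under 0.05. In all 158 the 3 treated arrays lay on one side of the 3 basal arrays, which a call at this threshold all but requires, so it adds no support. Over all genes that share was 23.3%, where chance gives 10%. The change was at least 2-fold in 108 of them (46 higher, 62 lower), and the median fold was 2.26. Other probe sets existed for 46 of the 158 genes and all had the same sign in 41. EED, to which the annotation assigns 23 probe sets, had 14 of the 22 others with the same sign, 1 of them also called, and 2 that moved the opposite way at an unadjusted p under 0.05. Among single probe sets 158 of 24016 passed, 73 higher and 85 lower. A further quantile normalization gave 57 higher and 43 lower. Of the 158 probe sets, 107 carried a single gene name, 2 several and 49 none. The exact permutation test of any single gene cannot give a p below 0.1 with 3 arrays against 3. The gene count was 1 without basal 1, 0 without basal 2 (limma, 1010 genes at an unadjusted p under 0.05) and 1538 without basal 3, then 3 without TGFB1 1, 0 without TGFB1 2 (1046 genes) and 8 without TGFB1 3. Setting basal 1, basal 2 and TGFB1 1 against the other arrays gave 1226 genes. Among the 155 genes covered by the naming rule, 35 that had not passed did so with these array sets as a block, a fit chosen after the data were seen and no independent test. Without basal 3 that number was 36. The basal arrays left then lie in the same array set and TGFB1 2 and TGFB1 3 in the other, so that fit mixes treatment with the array split. Of those named below without a call, MANF, FDPS, JUNB, PLOD2, COL4A1, POSTN, MMP9, BMP2, DDAH2 and PECAM1 passed in both of these fits. KLF10, PMEPA1, ENG, VCAN, the gene TGFB1 and EPB42 passed in the block fit alone, and BMPER, ID1, ID3, ACVRL1, ATF3 and CDH5 without basal 3 alone. With array weights 82 that had not passed did so in the same direction, and NOS3 did so with a changed sign. However, the estimation of these weights did not converge and gave 29.9 to basal 2 against 0.175 to 1.83 for the others. Values with array weights here and below therefore rest largely on basal 2 for the basal level.

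**Figure D2:**
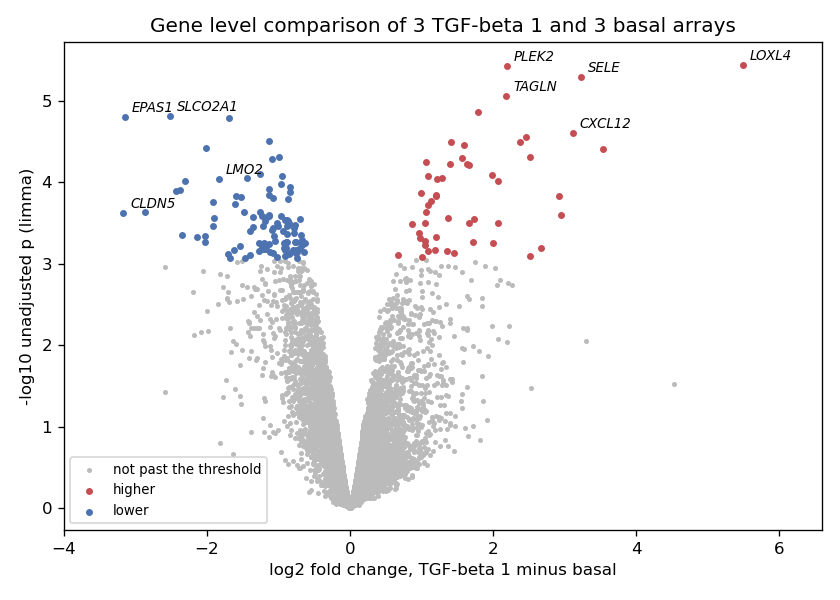
Each point is 1 of the 9162 genes, with the log2 fold change of TGF-beta 1 minus basal on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. The 51 genes past the adjusted threshold and higher are red, the 107 lower are blue, and LOXL4 at 5.50 and CLDN5 at -3.17 are the farthest of the called genes on either side.

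Among the other genes with the largest rises, GAS2, a binding partner of actin and microtubules, rose 11.6-fold (6.55 to 20.6) from a basal mean of 4.66 log2, near the 25th percentile of the arrays (4.52 to 4.60). The RMA values carry no detection call, so this basal level was not shown to be above background and the fold depends on it. Basal means of LOXL4, SELE, TGFBI and ATP1B1, from 5.18 to 5.80, lay below the array medians too. RGCC, a cell cycle regulator, rose 7.72-fold (3.99 to 14.9). VEGFA, the main angiogenic growth factor, rose 7.55-fold (4.17 to 13.7) and TGFBI, a secreted matrix protein named for its induction by TGF-beta, rose 6.40-fold (3.15 to 13.0). The secreted proteins CCDC80 and ANGPTL4 each rose 5.70-fold, with intervals of 3.74 to 8.69 and 2.85 to 11.4. ATP1B1, a subunit of the sodium pump, rose 5.53-fold, the LIM protein CSRP2 rose 5.19-fold and PLEK2, a pleckstrin, rose 4.59-fold. Limma adjusted p for these genes lay between 0.0155 for PLEK2 and 0.0484 for ANGPTL4.

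Among the largest falls, PGF, the placental growth factor, fell 7.30-fold (3.89 to 13.7), and the prostaglandin carrier SLCO2A1 fell 5.72-fold (4.04 to 8.09). FABP4, a fatty acid binding protein of capillary endothelium and adipocytes, fell 5.38-fold from the high basal level of 12.60 ± 0.29 log2. The organic anion carrier SLCO2B1 fell 5.20-fold and AOC3, an amine oxidase that serves as a vascular adhesion protein, fell 5.09-fold. PPP1R16B, a phosphatase subunit of endothelial cells, fell 4.93-fold, PEG10 and the selenium carrier SELENOP each fell 4.07-fold and QPRT, an enzyme of NAD synthesis, fell 4.05-fold to a treated mean of 4.42, below the 25th percentile of the arrays. CSF2, a myeloid growth factor, fell 3.78-fold (2.40 to 5.94). Limma adjusted p for these genes lay between 0.0188 for SLCO2A1 and 0.0441 for PEG10.

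**Figure D3:**
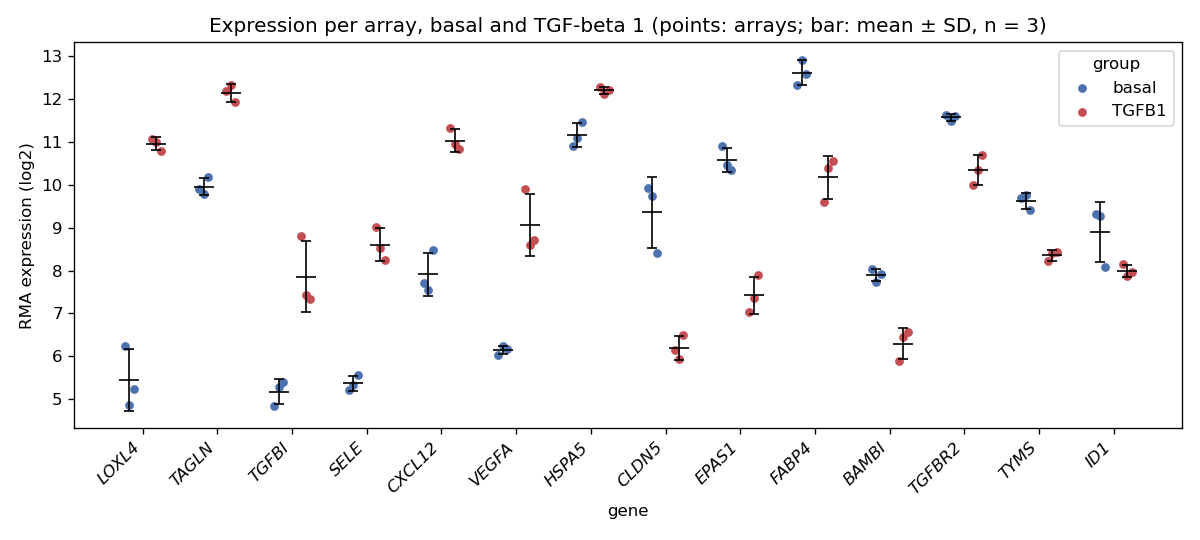
Expression (log2, vertical axis) of 14 genes on each of the 3 basal (blue) and 3 TGFB1 (red) arrays, where points are arrays and bars are the mean ± SD. LOXL4 has means of 5.45 and 10.96 and CLDN5 of 9.36 and 6.19, while for ID1 basal 3 at 8.09 lies among the treated arrays.

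Of the gene lists, 13 of 32 shifted as a whole by limma's camera test, 8 upward and 5 downward. The test presets a correlation of 0.01 between genes. With the correlation estimated from the residuals, only the list for endoplasmic reticulum stress and secretion kept its call. The estimate for the mesenchymal list was 0.0074, below the preset 0.01, yet its adjusted p rose from 0.000251 to 0.123 by camera. For inflammation it was 0.011, and that call ended too. The lost calls therefore cannot be read as an effect of correlation between genes alone. By fry, which does not compare a list with other genes, 8 of the 13 calls ended. The fry adjusted p was 0.12 for cholesterol synthesis, BMP and ALK1 targets and Notch, 0.142 for SMAD2/3 targets, glycolysis and interferon, 0.244 for YAP/TAZ and 0.0528 for reactive oxygen. Every other split of the 6 arrays into 3 and 3 also gave list calls by camera, from 1 to 11. Of the 712 measured list genes, 28 stood in more than 1 list. Members are also counted below adjusted over the list alone. In that way 4 of 16 housekeeping genes, a technical comparison, rose and 1 fell, while none of 42 ribosomal protein genes did. Such a count does not by itself mark a pathway.

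The list for endoplasmic reticulum stress and secretion shifted up as a whole. Of 27 measured members 2 rose and none fell over all genes tested, and 12 rose adjusted over the list alone. The mean log2 fold change was 0.60 (camera adjusted p = 4.94e-11, and adjusted p = 0.0435 with an estimated correlation). The chaperones HYOU1 and HSPA5 each rose, both by 1.05 log2 (SE 0.15 and 0.16, limma adjusted p = 0.0371 and 0.0449). Of the 4 other probe sets of HYOU1, 3 had the same sign and none was called. MANF, a secreted stress protein, stood at 1.01 (SE 0.20) with a limma adjusted p = 0.0743.

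The cell cycle and DNA replication list shifted down as a whole. Of 42 measured members 3 fell and none rose over all genes, and 19 fell adjusted over the list alone. The mean was -0.50 (camera adjusted p = 3.45e-08, adjusted p = 0.123 with an estimated correlation). TYMS, which makes thymidylate for DNA synthesis, fell by 1.26 log2 (SE 0.14). The mitotic regulators CDC20 and CCNB2 fell by 1.00 (SE 0.14) and 0.88 (SE 0.12), with limma adjusted p = 0.0371 for both.

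Genes of cholesterol and fatty acid synthesis shifted down by a mean of -0.51 (camera adjusted p = 0.000251, adjusted p = 0.523 with an estimated correlation). Of 22 members 2 fell and none rose, and 4 fell adjusted over the list alone. Squalene synthase FDFT1 fell by 1.16 log2 (SE 0.16) and the sterol isomerase EBP fell by 1.08 (SE 0.17). Of the 2 other probe sets of FDFT1, 1 had the same sign and none was called. FDPS, which makes the farnesyl precursor, stood at -0.65 (SE 0.13, limma adjusted p = 0.0728).

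The mesenchymal and contractile list shifted up by a mean of 0.40 (camera adjusted p = 0.000251, adjusted p = 0.123 with an estimated correlation). Of its 28 members 2 rose and none fell, over all genes and adjusted over the list alone. TAGLN, an actin-binding protein of contractile cells, rose by 2.19 log2 (SE 0.16, limma adjusted p = 0.0188), and the transcription factor SNAI1 rose by 1.01 (SE 0.17, limma adjusted p = 0.0487). ACTA2, the smooth muscle actin, stood at 0.20 (SE 0.41) and at -0.15 when the array sets above were kept as a block. With array weights, which did not converge, ACTA2 stood at 0.73 (limma adjusted p = 0.0091, up to 1.0 over its alternatives). Smooth muscle markers, of which 4 of 9 also stand in the mesenchymal list, had a mean of 0.26 (camera adjusted p = 0.234). TAGLN was the 1 member of that list that rose, over all genes and adjusted over the list alone, and none fell. SMTN stood at -0.26, MYH11 at -0.10 and CNN1 at 0.09.

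The SMAD2/3 list, direct targets of the canonical TGF-beta pathway, had a mean of 0.75 (camera adjusted p = 0.000356, adjusted p = 0.523 with an estimated correlation). The list median was 0.43. Array weights ended the call (0.0922), and adjusted p ran from 1.94e-07 to 0.523 over the alternatives. Of 12 measured members TGFBI alone rose over all genes, and 4 rose adjusted over the list alone. JUNB stood at 1.39 (SE 0.32), KLF10 at 0.44 (SE 0.11) and the feedback regulator PMEPA1 at 1.73 (SE 0.47), none past the limma threshold over all genes. With the array sets as a block these passed (limma adjusted p = 0.00274, 0.0432 and 0.00989), and 7 of the 12 members were called. JUNB also passed without basal 3 (0.0424). Over the alternatives their adjusted p ran from 0.00157 to 0.282 for JUNB, 0.00081 to 0.357 for KLF10 and 0.00989 to 0.327 for PMEPA1, with the lowest of JUNB and KLF10 from array weights. CCN2, a matricellular growth factor, stood at 0.04 (SE 0.09) from a basal level of 13.46 ± 0.02 log2, near the top of the range of the array. SMAD6 and SMAD7 were not analysed here.

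BMP and ALK1 targets had a mean of -0.65 (camera adjusted p = 0.034, adjusted p = 0.523 with an estimated correlation). The list median was -0.31. BAMBI, a decoy receptor, fell by 1.60 log2 (SE 0.20, limma adjusted p = 0.0321) and was the 1 of 9 members past the threshold, over all genes and adjusted over the list alone. BMPER stood at -2.59 (SE 0.98), ID1 at -0.90 (SE 0.34) and the co-receptor ENG at 0.99 (SE 0.38), with limma adjusted p = 0.25, 0.255 and 0.253. The 1 other probe set of BMPER did not share its sign, though it did not move the opposite way at an unadjusted p under 0.05. ID3 stood at -0.76 and ID2 at -0.31. In basal 3 ID1 lay at 8.09 and ID3 at 9.14 log2, against treated means of 8.0 and 9.05. Without basal 3 BMPER, ID1 and ID3 passed at -3.71, -1.30 and -1.10 (limma adjusted p = 0.00934, 0.00695 and 0.0102, up to 0.591, 0.603 and 0.603 over their alternatives). That fit mixes treatment with the array split. With the array sets as a block BMPER and ID1 stood at -1.82 and -0.66 and did not pass (limma adjusted p = 0.0548 and 0.117). ENG, which lay on the other side, passed at 1.29 with the array sets as a block (0.0117) and was called with array weights (0.0305), with up to 0.518 over its alternatives. The camera call ended with the array sets as a block (adjusted p = 0.0837), and without basal 1 (0.0814), TGFB1 2 (0.0529) or TGFB1 3 (0.0548). It also ended with array weights (0.0661) and among probe sets above the median (0.103), and over all alternatives the adjusted p ran from 0.0136 to 0.523.

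Of 22 ligands, receptors and SMADs of the pathway, TGFBR2 alone passed over all genes, falling by 1.23 log2 (SE 0.19, limma adjusted p = 0.0461). In all 1 rose and 1 fell adjusted over the list alone. BMP2 stood at 0.69, TGFBR1 at 0.49, TGFB1 at 0.36 and ACVRL1 at -0.89. The gene TGFB1 stood at 0.05 without the array TGFB1 1 and 0.10 without basal 3, and passed at 0.65 with the array sets as a block (limma adjusted p = 0.0247, up to 0.945 over its alternatives). ACVRL1 passed at -1.28 without basal 3 (0.00819, and from 0.00039 with array weights to 0.590 over its alternatives). The list mean was 0.08 (camera adjusted p = 0.465).

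Collagens and their modifying enzymes shifted up by a mean of 0.45 (camera adjusted p = 0.00164, adjusted p = 0.462 with an estimated correlation). The list median was 0.17. LOXL4 was the 1 of 27 members that rose, none fell, and 4 rose adjusted over the list alone. PLOD2, a lysyl hydroxylase, stood at 1.84 (SE 0.38) and the basement membrane chain COL4A1 at 0.47 (SE 0.10), while COL1A1 stood at 0.04 (SE 0.16). None of the 36 members of the other extracellular matrix list passed, over all genes or adjusted over the list alone (limma, camera adjusted p = 0.543, mean -0.07). In that list POSTN stood at 2.22 (SE 0.42, limma adjusted p = 0.0669), VCAN at -1.68 (SE 0.41) and FN1, near the top of the range, at 0.07 (SE 0.10). Of 32 proteases and inhibitors S100A10, a plasminogen-binding protein, fell by 0.83 log2 (SE 0.10) and none rose. Adjusted over the list alone 1 rose and 1 fell. MMP9 stood at 2.10 (SE 0.39, limma adjusted p = 0.0657), and the list mean was -0.07 (camera adjusted p = 0.633). Of 24 integrin and junction genes the integrin subunit ITGAV rose by 2.01 log2 (SE 0.31, limma adjusted p = 0.0441) and none fell. Adjusted over the list alone 5 rose and 4 fell, and the list mean was 0.15 (camera adjusted p = 0.294).

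Genes of inflammation and leukocyte adhesion shifted up by a mean of 0.63 (camera adjusted p = 0.000255, adjusted p = 0.123 with an estimated correlation). Of 36 members 2 rose, SELE and CXCL12, and 3 fell. As many as 9 rose and 4 fell adjusted over the list alone. The junctional adhesion molecules JAM2 and F11R, which also serve leukocyte passage, fell by 1.92 (SE 0.24) and 0.86 (SE 0.12) log2, and CSF2 was the third that fell.

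Endothelial identity genes had a mean of -0.32 and no camera call (adjusted p = 0.0757), but the list was called without basal 1 (0.0331), with limma-trend (0.0448) and with the mean of the probe sets of a gene (0.0450). Its adjusted p ran from 0.0331 to 0.576 over the alternatives. Of 37 members 1 rose and 5 fell, with 2 and 9 adjusted over the list alone. CLDN5, the transcription factors LMO2 (-1.82, SE 0.20) and HHEX (-1.23), the surface protein CD93 (-1.23, SE 0.19) and the receptor activity protein RAMP2 (-1.40) fell. The adhesion receptor ADGRF5 rose by 1.06 (SE 0.11). PECAM1 stood at -0.52, CDH5 at -0.57, KDR at -0.67 and VWF at -0.17, none past the limma threshold over all genes. Without basal 3 PECAM1 passed at -0.62 and CDH5 at -0.74 (limma adjusted p = 0.0218 and 0.0322, up to 0.366 and 0.523 over their alternatives), and PECAM1 also passed with the array sets as a block (0.0439). NOS3, the endothelial nitric oxide synthase, stood at 0.11 (SE 0.47), at -0.38 without basal 3 and -0.18 without TGFB1 1, at 0.42 without basal 2 and at 0.49 with the array sets as a block. With array weights it stood at -0.705 (limma adjusted p = 0.0177, up to 0.945 over its alternatives). Of 24 vasoactive mediators none passed over all genes (limma) and DDAH2 was the 1 that fell adjusted over the list alone, at -0.87 (SE 0.15). The list mean was -0.06 (camera adjusted p = 0.604), with EDN1 at 0.15 (SE 0.11) near the top of the range.

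Growth factors and angiogenesis genes had a mean of -0.15 (camera adjusted p = 0.0898). Of 31 members VEGFA and ANGPTL4 rose, and PGF and IGFBP3, a carrier of insulin-like growth factors, fell, the latter by 1.06 log2 (SE 0.16). The list was called among probe sets above the 25th percentile (0.0386), on ranks (0.0465) and by fry (0.0352), and its adjusted p ran up to 0.503 over the alternatives. Adjusted over the list alone 3 rose and 6 fell.

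Glycolysis and hypoxia genes shifted up by a mean of 0.16 (camera adjusted p = 0.00164, adjusted p = 0.503 with an estimated correlation). Of 29 members the stress regulator DDIT4 rose by 1.41 log2 (SE 0.13), the glucose carrier SLC2A1 rose by 1.05 (SE 0.16) and EPAS1 fell. In this list 7 rose and 1 fell adjusted over the list alone. Interferon response genes had a mean of 0.34 (camera adjusted p = 0.022, adjusted p = 0.523 with an estimated correlation), and of 24 members IFI6 rose by 1.10 (SE 0.14) and the RNA-activated kinase EIF2AK2 by 1.18 (SE 0.19). Among interferon genes 4 rose and 1 fell adjusted over the list alone. Without basal 3 the glycolysis call ended at camera adjusted p = 0.0583 and the interferon call at 0.1, and without TGFB1 3 the interferon call ended at 0.0567. Array weights ended the glycolysis call (0.203), and keeping probe sets above the median ended the interferon call (0.0563). Over the alternatives adjusted p ran from 0.00017 to 0.503 for glycolysis and from 0.00268 to 0.523 for interferon.

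YAP/TAZ and SRF targets had a mean of 0.30 (camera adjusted p = 0.0377, adjusted p = 0.523 with an estimated correlation). The list median was 0.08. Of 14 members, 6 of which also stand in other lists, the kinase NUAK2 rose by 1.57 log2 (SE 0.16), FHL2 rose by 1.13 (SE 0.14) and FHL1, another LIM protein, fell by 1.13 (SE 0.10). Adjusted over the list alone 3 rose and 1 fell. Of 9 Notch pathway genes LFNG, a glycosyltransferase of Notch receptors, fell by 1.36 log2 (SE 0.19), and was the 1 call over all genes and adjusted over the list alone. The Notch list mean was -0.38 (camera adjusted p = 0.034, adjusted p = 0.523 with an estimated correlation). Of 40 reactive oxygen and antioxidant genes UCP2, a mitochondrial carrier, fell by 0.87 log2 (SE 0.12), again the 1 call over all genes and adjusted over the list alone. The mean was -0.19 (camera adjusted p = 0.034, adjusted p = 0.523 with an estimated correlation), and NOX4, an oxidase that makes hydrogen peroxide, stood at 0.49 (SE 0.29). Without basal 3 these calls ended, at camera adjusted p = 0.199 for YAP/TAZ, 0.0533 for Notch and 0.0791 for reactive oxygen. They also ended for YAP/TAZ without TGFB1 1 (0.129) or TGFB1 3 (0.0534), for Notch without basal 1 (0.0623) or TGFB1 2 (0.0697) and for reactive oxygen without TGFB1 1 (0.0646). Array weights ended them at 0.411, 0.0546 and 0.0865 and keeping probe sets above the median at 0.0813, 0.0813 and 0.0715, in the same order. For YAP/TAZ probe sets above the 25th percentile (0.0532) and ranks (0.0688) also ended the call, and for reactive oxygen the mean of a gene's probe sets did (0.058). Over the alternatives adjusted p ran up to 0.523 for all of these lists, from 0.00463 for YAP/TAZ, 0.0213 for Notch and 0.0288 for reactive oxygen.

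**Figure D4:**
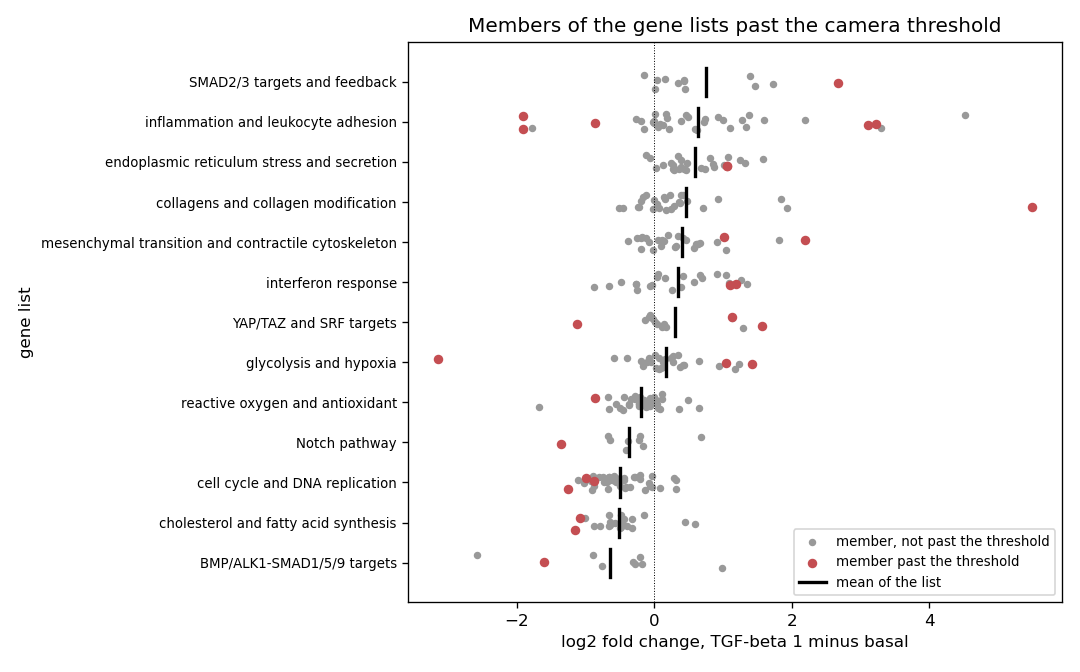
Log2 fold change, TGF-beta 1 minus basal (horizontal axis), of the members of the 13 gene lists past the camera threshold (vertical axis), where points are genes, red points passed the limma threshold over all genes and black bars are list means. Means run from -0.65 for BMP and ALK1 targets to 0.75 for SMAD2/3 targets, and LOXL4 at 5.50 stands apart from the other 26 members of the collagen list.

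Markers of other cells of the aorta gave no list call, except that erythroid markers were called among probe sets above the 25th percentile (mean 0.34, camera adjusted p = 0.0424, up to 0.610 over the alternatives). In that list EPB42, an erythrocyte membrane protein, stood at 1.17 (SE 0.30, limma adjusted p = 0.115) and passed with the array sets as a block (0.0121, and from 0.00128 with array weights to 0.345 over its alternatives). Of 21 fibroblast markers CCDC80 rose and CLEC3B, a plasminogen-binding lectin, fell by 0.96 log2 (SE 0.13), over all genes and adjusted over the list alone (mean 0.06, camera adjusted p = 0.919). FABP4 was the 1 of 9 adipocyte markers that fell, 2 fell adjusted over the list alone and none rose (mean -0.38, camera adjusted p = 0.256). No gene passed limma over all genes or adjusted over the list alone among 6 pericyte (camera adjusted p = 0.817), 17 leukocyte (0.947), 8 erythroid (0.165) and 13 epithelial or mesothelial markers (0.972). Of 17 immediate early genes none passed over all genes, and 2 rose adjusted over the list alone, JUNB and ATF3 (camera adjusted p = 0.650). None of 13 apoptosis genes (0.612), 42 ribosomal protein genes (0.631) or 45 respiratory chain genes (0.947) passed in either way. Of 16 housekeeping genes none passed over all genes (0.383), and adjusted over the list alone 4 rose and 1 fell. In 9 of the lists without a call the mean, the median and the camera direction differed in sign, and in none with a call. These were other extracellular matrix, vasoactive mediators, apoptosis, ribosomal proteins, immediate early genes, respiratory chain, and the pericyte, fibroblast and epithelial markers.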

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

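The fit with the array split as a block was chosen after the data were seen, and the other alternatives were planned. Of 2450 alternative values for named genes 1951 kept their direction and side of the limma threshold, 329 fell below it, 155 passed it in the same direction and 15 changed sign, among them NOS3 with array weights, which also passed. Values that never passed count among those kept. Among the 155 named genes, leaving out any 1 array other than basal 3 ended 46 to 53 calls, and leaving out basal 3 ended 0. For the lists the numbers were 482, 50, 7 and 31 of 570. The gene count of 158 stayed between 134 and 160 with a further quantile normalization, centring on array medians, robust eBayes, filters on dim probe sets, a minimum of 1.5-fold or another representative probe set. Further quantile normalization gave 100 probe sets and limma-trend 87 probe sets (60.9% higher, against 46.2%) and 99 genes (42.4% higher, against 32.3%), and the cause was not tested. A threshold of 0.1 gave 543 probe sets and 433 genes, a threshold of 0.01 gave 2 and 0 (limma, 3289 and 1598 at an unadjusted p under 0.05), and treat against 1.2-fold gave 27 and 34. Array weights, which did not converge, gave 11350 probe sets, 4989 genes and 7 lists, with a weight of 29.9 for basal 2 and 0.175 to 1.83 for the others. Whether the replicate numbers pair the arrays is not known: the correlation of same-numbered deviations from the group means was 0.67, -0.45 and 0.69, signs that also follow the array split, and 4 of 6 arrays matched their own number best. With the replicate number as a block limma called 0 probe sets (4450 at an unadjusted p under 0.05), 0 genes (2039) and 12 lists, the call of YAP/TAZ targets ending (0.0544). With the array split as a block it called 1348 probe sets, 878 genes and 12 lists. Leaving out 1 array gave 1 to 2012 probe sets, 0 to 1538 genes and 8 to 13 lists. Probe sets numbered 2 without basal 1, 1 without basal 2, 2012 without basal 3, 12 without TGFB1 1 and 1 without TGFB1 2 or TGFB1 3. Genes numbered 1, 0 (1010 at an unadjusted p under 0.05), 1538, 3, 0 (1046) and 8 in the same order of arrays, and lists numbered 8 without basal 3. The cause of these moves was not tested. Lists numbered 8 among probe sets above the median, 1 with an estimated correlation and 6 by fry, which does not compare a list with other genes. Robust eBayes was not run for lists, since camera has no such setting. The first component held 68.2% over the 1000 most variable probe sets.

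All sign changes were in values that had not passed the threshold, and their cause was not tested. With array weights NOS3 stood at -0.705 (called, limma adjusted p = 0.0177, up to 0.945 over its alternatives), COL1A1 at -0.0127 and TGFB1 at -0.0133, and list means were -0.0633 for TGF-beta ligands and receptors, -0.0174 for integrins, -0.118 for immediate early genes and -0.0920 for apoptosis. The respiratory chain mean was -0.00686 and the apoptosis mean -0.00185 after quantile normalization, and -0.00139 and -0.00408 after centring. Leukocyte markers had a mean of 0.00541 above the 25th percentile and apoptosis -0.0636 above the median. With the array split as a block means were 0.00320 for vasoactive mediators, -0.0438 for the respiratory chain, -0.0126 for ribosomal proteins, 0.0980 for pericyte and 0.000442 for epithelial markers, with ANPEP at 0.0589 and ACTA2 at -0.150. With the mean of a gene's probe sets the respiratory chain was at -0.00201 and pericyte markers at 0.00684. Leaving out 1 array moved the list means from -0.0586 (without basal 1) to 0.0743 for the respiratory chain, -0.0234 (basal 1) to 0.0496 for ribosomal proteins, -0.127 to 0.0996 (basal 1) for pericyte, -0.0910 to 0.00178 (basal 1) for epithelial markers, -0.0787 (TGFB1 1) to 0.160 for immediate early genes, -0.0326 (TGFB1 1) to 0.0508 for apoptosis and -0.00101 (TGFB1 1) to 0.125 for TGF-beta ligands and receptors. It moved ANPEP from -0.204 to 0.0704 (basal 1), NOS3 from -0.381 (basal 3) to 0.423, COL1A1 from -0.100 (basal 3) to 0.170, RGS5 from -0.0115 (TGFB1 1) to 0.146, KCNJ8 from -0.0103 (TGFB1 1) to 0.126 and ACTA2 from -0.00066 (TGFB1 2) to 0.586. The RMA values carry no detection call, and changes near background or near the top of the range are limited by the signal of the array.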

Other observations

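Several genes outside the lists also passed the limma threshold, and the following were chosen after their values were seen. The protease-activated receptor F2RL1 rose by 2.07 log2 (SE 0.23), the purine receptor P2RY1 by 1.80 (SE 0.14), the oxidised lipoprotein receptor OLR1 by 1.38 (SE 0.19) and KITLG, the ligand of the KIT receptor, by 1.66 (SE 0.17). The fibrillar collagen COL27A1, which the collagen list did not hold, rose by 1.98 (SE 0.22). SULT1A1, a sulfotransferase, fell by 1.68 log2 (SE 0.14), MGST1, a membrane glutathione transferase, fell by 1.62 (SE 0.26) and the aldehyde dehydrogenase ALDH2 fell by 0.94 (SE 0.14). STMN1, a microtubule regulator of dividing cells, fell by 0.99 (SE 0.10) and the chromatin protein HMGB2 fell by 0.78 (SE 0.11). Limma adjusted p for these genes lay between 0.0188 for P2RY1 and SULT1A1 and 0.0461 for MGST1. For each the 3 arrays of a group lay on one side of the other 3, which such a call all but requires.

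The tests of MHC probe sets, labelled RNA length, TAGLN and basal 3 and the counts of splits for genes and probe sets were chosen after the results were seen, and the bounds for RNA length and the test of basal 3 were reset after their values were known. With the bounds first set, on the median alone, labelled RNA length would have been excluded and basal 3 would have met the bound set for a treated culture, which took no account of the array split.

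The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 158 probe sets and the highest other 2866, so 2 of the 10 gave as many. For genes the values were 158 and 1226, again 2 of the 10, and for lists 13 and 11, which 1 of the 10 reached. The 8 splits other than these gave 0 genes by limma, with 23 to 173 genes at an unadjusted p under 0.05. Those 8 splits still gave 2 to 11 lists by camera. The split with 1226 genes set basal 1, basal 2 and TGFB1 1 against basal 3, TGFB1 2 and TGFB1 3, and so many genes point to a structure of the samples. With it as a block 878 genes passed for treatment, 367 higher and 511 lower, among them all 158 of the fit without it. That block was drawn from these values, so its count is no independent test.

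The array sets differed by several log2 units in genes picked after seeing the values. ECM1 read 9.64, 9.78 and 8.19 on basal 1, basal 2 and TGFB1 1 against 6.18, 6.27 and 5.67 on basal 3, TGFB1 2 and TGFB1 3, and CDH2, N-cadherin, read 5.02, 4.89 and 5.72 against 7.72, 8.56 and 8.81. An artefact of single probe sets is argued against, since the difference between array sets in a pair of probe sets of a gene correlated at 0.817 across 1324 genes, near the 0.818 of the treatment difference. Cells from different animals remain possible but untested by the labels. Of 15 bright MHC probe sets, whose sequence varies between animals, 1 (6.67%) was among the 5% that parted the array sets most, with a difference of 1.51 log2. With the probe set first noticed the share was 12.5% of 16. That probe set read 4.2, 4.2 and 3.7 on basal 1, basal 2 and TGFB1 1 against 7.6, 7.5 and 7.1 on basal 3, TGFB1 2 and TGFB1 3. The other bright MHC probe sets were not among the 5%. Shorter labelled RNA stays open too, as the gap between 3' and 5' control probe sets moved by a median of -0.0067, with 0.60 for EEF1A1 and -0.38 for EIF4E going opposite ways and GAPDH and cyclophilin near 0 at -0.06 and 0.05, so that no value was shared by all 4.

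TAGLN rose by 2.19 log2, and smooth muscle cells in the treated cultures could bring it. The lower 95% limit of TAGLN, 1.79, exceeded the upper limit of ACTA2, 1.21, by 0.58. Added smooth muscle cells would raise both genes alike only if both started equally far below their level in such cells. That level was not measured, so the gap does not decide whether such cells contributed. That gap was above 0 in each limma fit of single genes run here other than treat, from 0.22 without TGFB1 1 to 1.66 with the array sets as a block, and 1.03 with array weights, which did not converge and put ACTA2 at 0.73 (limma adjusted p = 0.0091, up to 1.0 over its alternatives). A response of the endothelial cells to TGF-beta 1, which the design names, stays open as a hypothesis and was not tested apart from other causes.

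ID1 and ID3 in basal 3 lay at 0.93 and 0.91 of the way from the other basal arrays to the treated mean, so basal 3 may have been a treated culture. Yet of 627 genes at least 2-fold apart between TGFB1 1 and the mean of basal 1 and basal 2, 94.7% parted TGFB1 2 and TGFB1 3 from basal 3 in the same direction, against 39.7% for TGFB1 3 minus TGFB1 2. That argues against a culture treated like TGFB1 2 and TGFB1 3, which would part from them in either direction alike. A weaker or shorter exposure of basal 3 to TGF-beta stays open, as does the structure of the array sets: in these genes the median change was 1.34 log2 in TGFB1 1 and 0.63 in TGFB1 2 and TGFB1 3 minus basal 3, where a partial exposure would lower the second value, and so would picking the genes in TGFB1 1. Over the 1538 genes called without basal 3 its median position was 0.713, with 29.1% nearer the other basal arrays, which decides nothing between these, since the array split alone could place it there. BMPER put basal 3 at 0.91, but LOXL4, SELE, EPAS1, TGFBI and TAGLN put it at -0.06, 0.08, 0.10, 0.12 and 0.15. The latter genes decide nothing either, as they passed with basal 3 counted as basal, which favours genes in which it lies near the other basal arrays.

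Control probe sets were also compared between the groups. Of 112 none passed limma's threshold, with 7 at an unadjusted p under 0.05 and a smallest adjusted p of 0.527.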
